A study of Homo sapiens with 9 samples.

How the data were processed

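RNA was measured in cultured human dermal lymphatic endothelial cells, primary cells that line the lymphatic vessels of the skin. Per the labels' protocols, cells received 40 nM of a control siRNA (siControl), an siRNA against PROX1 (siPROX1) or an siRNA against TIE2 (siTIE2, the receptor encoded by TEK) for 24 h and were harvested after 72 h. Total RNA was made into libraries with a Lexogen mRNA-Seq kit, per the labels' protocols. Each of the 3 groups holds 3 libraries, numbered 1 to 3 in the labels. Nothing in the labels says whether the replicates came from separate cultures, transfections or donors, so the p-values measure the spread between these libraries, which may be technical.

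The deposited files hold whole-number read counts per gene symbol, 1 file per library, not normalized. The submitters' processing notes name TopHat2 2.0.9, edgeR and the human build hg19, with no role or order. The program that counted reads, the gene annotation and the use of strand are not given in the sources used here, so overlapping and antisense genes cannot be told apart and the names of such genes were passed over. Every file lists the same 26364 symbols. Of these, 23795 are current symbols in the reference gene tables for GRCh38, 1466 are synonyms only and 1103 matched neither. The reference was used for names, GC content and transcript length, and no coordinates are given because its build differs from that of the files. In all 9 libraries even counts outnumbered odd ones among genes with 2 to 11 counts, by 1.57 to 1.9 times, so a count need not stand for 1 independent fragment.

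Total counts of replicates 1, 2 and 3 were 113158594, 137288574 and 156382832 in siControl, 87030670, 95914030 and 106902411 in siPROX1 and 97688740, 90252538 and 93337515 in siTIE2. Every control library was deeper than every knockdown library, so depth and treatment are confounded. The 10 most abundant genes took 6.63 to 7.7% of the counts, and normalization factors lay between 0.956 and 1.028. No pair of libraries within a group agreed within sampling noise, and all were kept as separate replicates. Deviations from the group means correlated at 0.112 to 0.24 between same-numbered siPROX1 and siTIE2 libraries and at −0.159 to −0.022 between differently numbered ones. From these values, and not from the labels, the numbers were taken to pair siPROX1 with siTIE2. The highest of these values, 0.24, is that of the replicates numbered 1, which also share genes absent from the other siTIE2 libraries. That value may come from mixed reads. Deviations within a group sum to 0, so values above 0 for same numbers push the others below 0. The differently numbered siControl replicate 1 and siPROX1 replicate 3 reached 0.27. The pairing is therefore uncertain. The fit with the replicate number as a block was made over all 9 libraries.

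Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest) on the deposited counts, with TMM normalization and filterByExpr, which left 16815 genes. All 9 libraries entered 1 fit with 1 coefficient per group, so the 3 comparisons shared 1 estimate of the spread (common biological coefficient of variation 0.229, prior degrees of freedom 3.63). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Levels are TMM-scaled CPM, counts relative to the effective library size, given as mean ± SD over the 3 libraries. Log2 fold changes carry an approximate standard error (SE). It is the size of the log2 fold change divided by the square root of the quasi-likelihood F statistic. For a gene with no count in the control libraries the fold is a lower bound against a floor of 3 counts over the group, and floors cover counting error only. The floor takes each count as 1 fragment, which the even counts leave in doubt, so the bound may be too high.

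A total of 24 gene lists were written from general knowledge before the data were examined: lymphatic, blood and pan-endothelial identity, angiopoietin-TIE and VEGF ligands and receptors, FOXO targets, Notch, lymphatic valve, junctions and barrier, G1/S, mitosis, interferon response, NF-kB, cholesterol synthesis, fatty acid oxidation, endothelial-mesenchymal transition and actin contractility, extracellular matrix, hypoxia and glycolysis, p53 targets, unfolded protein and ATF4 response, shear stress and KLF2/KLF4 targets, and markers of fibroblasts, smooth muscle and pericytes, keratinocytes and leukocytes. Some genes sit in several lists. Lists were tested against all other genes with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation, adjusted over the 24 lists by the Benjamini-Hochberg method. Calls of members are given over all genes tested and adjusted over the list alone.

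The rule for named genes was fixed with the lists. It took PROX1 and TEK, the 10 largest increases and 10 largest decreases against siControl (5 and 5 for siPROX1 against siTIE2) among called genes with at least 5 CPM in the higher group and no overlap between the 3 and 3 libraries, and, against siControl only, up to 4 members past the threshold per list and 13 endothelial genes reported whatever their result. Against siControl a list is described by its members where camera called it or at least 25% of its members passed. Other lists, and all lists between siPROX1 and siTIE2, are given as counts. Genes outside the rule are named as such, and 2 genes the rule took are not reported here.

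Alternatives fixed before the data were examined were RLE size factors, upper-quartile scaling, no low-count filter, a filter of at least 1 CPM in at least 6 libraries, the replicate number as a block, robust dispersion, DESeq2 1.42.0, a fit of only the 6 libraries compared, a threshold of 0.01, leaving out each library in turn, and for the gene lists an estimated correlation and fry in place of camera. Overlap of the knockdowns was set against 100 simulated pairs of unchanged groups, each pair sharing simulated controls. All simulated counts, controls included, were drawn from the mean siControl levels and the spread per gene estimated over all 9 libraries. Tests on simulated counts used 200 of 16815 genes changed. For siPROX1 against siControl the test recovered 65% of genes changed by 1 on the log2 scale and 98% of those changed by 2, with 3.55% of calls false. For siTIE2 against siControl it recovered 70% and 96%, with 3.49% false. The changed genes all had at least 1 CPM in siControl, and every group had the same spread per gene. In the data the siPROX1 libraries spread more, and 19% of genes were called in siPROX1 against siControl. These rates therefore need not hold for the data. Figures and library comparisons were made in Python 3.11.15.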

Results

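RNA was sequenced from human dermal lymphatic endothelial cells treated with a control siRNA, an siRNA against PROX1, the homeobox transcription factor that specifies lymphatic endothelium, or an siRNA against TIE2, the angiopoietin receptor encoded by TEK. Each group held 3 libraries, with 87030670 to 156382832 counts each, and all siControl libraries were deeper than all knockdown libraries. Of 26364 gene symbols, 16815 had enough counts for testing. The design asks which genes depend on each of the 2 targets, and how far both knockdowns share a response.

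TEK fell to 11.7% of its control level in siTIE2, from 197 ± 5.96 to 23 ± 1.24 CPM (SD, n = 3 libraries per group; log2 fold change −3.10, SE 0.18; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.59e-05). PROX1 fell less evenly in siPROX1: the 3 libraries held 328, 175 and 67.2 CPM, against 386, 642 and 521 CPM in siControl. Its log2 fold change was −1.44 (SE 0.45), at the edge of the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.05). Without siPROX1 replicate 1 it was −2.09 (edgeR, Benjamini-Hochberg adjusted p = 0.00495). The call was lost on leaving out any siControl or siTIE2 library or siPROX1 replicate 2 (edgeR, Benjamini-Hochberg adjusted p from 0.0649 to 0.148). PROX1 in siTIE2, 504.5 ± 41.9 CPM, differed from siControl by less than its error (log2 fold change −0.03, SE 0.44; 0.15 without siControl replicate 2 and 0.03 without siTIE2 replicate 3). TEK in siPROX1 was 284.6 ± 74.2 CPM, 0.53 above siControl on the log2 scale (SE 0.17; edgeR, Benjamini-Hochberg adjusted p = 0.0527), and passed the threshold without siPROX1 replicate 1 (0.71; edgeR, Benjamini-Hochberg adjusted p = 0.00227).

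**Figure D1:**
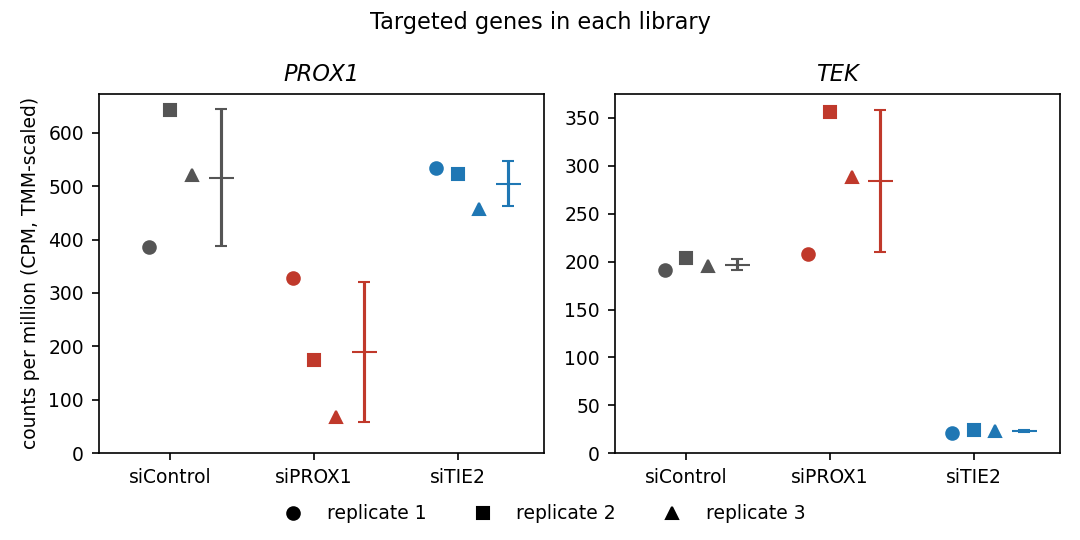
Levels of PROX1 and TEK in TMM-scaled CPM (vertical axes) in the siControl, siPROX1 and siTIE2 libraries, with points for single libraries and the mean ± SD of 3. TEK lies between 21.6 and 23.9 CPM in siTIE2 and between 192 and 203 CPM in siControl, and PROX1 spreads from 67.2 to 328 CPM in siPROX1.

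The siPROX1 libraries differed among themselves more than those of the other groups. ANGPT2, a TIE2 ligand, was at 377 CPM in siPROX1 replicate 1 and at 95.1 and 76.1 CPM in replicates 2 and 3. It was at 770.1 ± 4.49 CPM in siTIE2 and 266.8 ± 15.1 CPM in siControl. PDGFRB, a PDGF receptor of mural cells, was at 3.8 CPM in siPROX1 replicate 1 and at 0.654 and 0.664 CPM in the others. Across genes, which are not independent replicates, log2 CPM of siPROX1 replicate 1 correlated with siTIE2 replicate 1 at r = 0.991 and with siPROX1 replicates 2 and 3 at 0.992 and 0.979. The first principal component, 43% of the variance, placed siPROX1 replicates 1, 2 and 3 at 22.4, 63.5 and 105.3 and all other libraries between −39.6 and −27.2. Counts without siPROX1 replicate 1 are therefore given for the gene lists of siPROX1 against siControl.

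**Figure D2:**
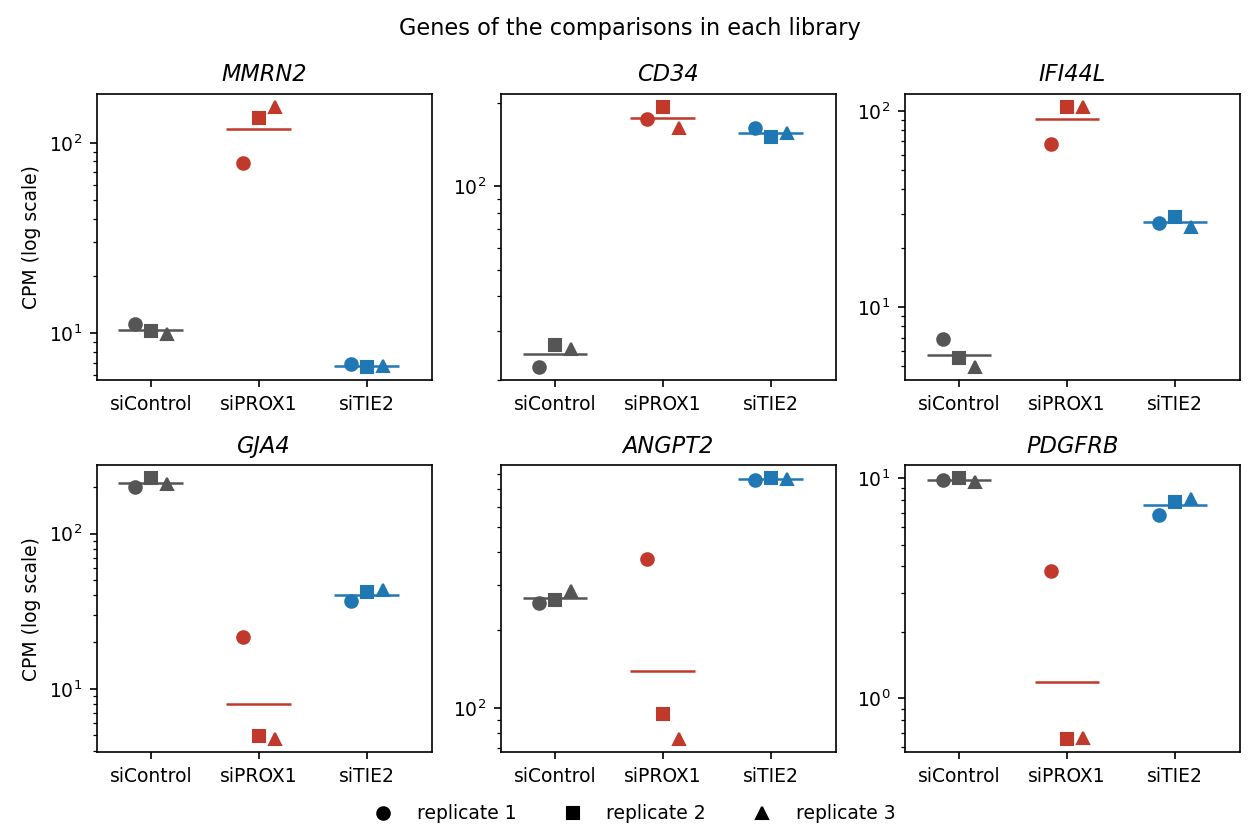
CPM of MMRN2, CD34, IFI44L, GJA4, ANGPT2 and PDGFRB in each library (points; vertical axes on a log scale; horizontal lines, geometric means of the 3 libraries) of siControl, siPROX1 and siTIE2. ANGPT2 in siPROX1 replicate 1, at 377 CPM, lies between the other siPROX1 libraries, at 95.1 and 76.1 CPM, and the siTIE2 libraries.

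Genes that were nearly silent in control cells rose in siPROX1. CLEC3B, which encodes the plasminogen-binding protein tetranectin, rose from 0.1133 ± 0.0702 to 89.69 ± 49.5 CPM (log2 fold change 9.68, SE 0.71), and DNASE1L3, a secreted nuclease, from 0.4105 ± 0.0793 to 53.22 ± 27.6 CPM (7.02, SE 0.71). FCN3, a lectin that starts complement activation, had no count in siControl and 9.181 ± 4.44 CPM in siPROX1. That is at least 1240-fold higher if each count is 1 fragment. CCL23, a chemokine, rose by 9.28, ACOX2, an enzyme of peroxisomal bile acid synthesis, by 6.27, and NOSTRIN, a regulator of endothelial nitric oxide synthase trafficking, by 5.43 (4.44 without siPROX1 replicate 3). TIMP4, CHN2, PKD1L1 and EXOC3L2 completed the 10 largest increases, with log2 fold changes of 5.43 to 6.81. Among controls CHN2 had counts in siControl replicate 1 alone, and its value was 6.15 or 6.09 without replicates 2 or 3; EXOC3L2 was at 7.10 without siControl replicate 2.

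GJA4, the gap junction protein connexin 37 of arterial and lymphatic valve endothelium, showed the largest decrease named by the rule, from 211.9 ± 13.9 to 10.39 ± 9.56 CPM (log2 fold change −4.35, SE 0.55; −5.45 without siPROX1 replicate 1). The sarcoglycan SGCD (−3.63), the Slit-Robo GTPase-activating protein SRGAP3 (−3.45) and the Wnt receptor FZD10 (−3.43) fell too, as did RIMS1, DSG2, IL20RA, ERRFI1, AKR1C2 and NTN1 (−3.22 to −2.65). With siPROX1 replicate 1 left out the values were −4.55 for SGCD (−3.04 without siPROX1 replicate 3), −4.13 for FZD10, −3.53 for DSG2, −3.63 for IL20RA and −3.61 for ERRFI1. These 20 genes had adjusted p from 1.08e-05 to 0.0107 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

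In all, 1890 genes rose and 1313 fell in siPROX1 against siControl, 947 and 448 of them by at least 2-fold, and the 3 and 3 libraries did not overlap for 34.2% of genes tested, where chance gives 10%. Leaving out siPROX1 replicate 1 gave 2146 and 1853. Without siControl replicates 1, 2 and 3 they were 1468 and 871, 1311 and 785, and 1203 and 716. In a fit of the siControl and siPROX1 libraries alone 1327 rose and 705 fell. That fit did not share the narrower spread of the siTIE2 libraries, and it held fewer libraries.

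Lymphatic identity genes moved unevenly in siPROX1. CCL21, the lymphatic chemokine that attracts dendritic cells, fell to 51.3% of control (log2 fold change −0.96, SE 0.10) and the hyaluronan receptor STAB2 to 49.9%. FOXC2, a transcription factor of lymphatic valves (−1.31, SE 0.24), and the secreted glycoprotein RELN (−1.83, SE 0.44) fell too, while the nuclear receptor NR2F2 rose by 0.57 (SE 0.10). LYVE1, a hyaluronan receptor, had a log2 fold change of −0.55 (−0.87 without siPROX1 replicate 1), PDPN, the membrane glycoprotein podoplanin, −0.11 (−0.33), and FLT4, the receptor VEGFR3, −0.14 (−0.08). LYVE1 and PDPN passed the threshold without that library (edgeR, Benjamini-Hochberg adjusted p = 0.000434 and 0.0468), and FLT4, SOX18 (−0.30) and ITGA9 (−0.02) did not pass either way. Of 22 list members, 1 rose and 7 fell, PROX1 among them (1 and 8 adjusted over the list alone), with a camera adjusted p of 0.047 and an adjusted p = 0.30 with an estimated correlation. Leaving out siPROX1 replicate 1, 1 rose and 9 fell (camera adjusted p = 0.0091). That camera call was lost without siControl replicates 1 or 2, siPROX1 replicates 2 or 3, or siTIE2 replicates 1 or 2 (adjusted p from 0.052 to 0.14). RELN was −2.59 without siPROX1 replicate 1 and missed the threshold without siControl replicates 2 or 3 or siPROX1 replicate 2 (edgeR, Benjamini-Hochberg adjusted p from 0.0539 to 0.0714). STAB2 missed it without siControl replicates 1 or 2 or siPROX1 replicates 1 or 2 (edgeR, Benjamini-Hochberg adjusted p from 0.052 to 0.0758).

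In the same cells 10 of 20 blood endothelial and 12 of 24 pan-endothelial genes rose. CD34, a sialomucin of blood endothelium, rose from 24.88 ± 2.41 to 177.3 ± 16 CPM (log2 fold change 2.83, SE 0.12), CXCR4, the CXCL12 receptor, by 2.51, FLT1, the receptor VEGFR1, by 2.17, and its ligand PGF by 2.12. The matrix protein MMRN2 rose from 10.41 ± 0.628 to 123 ± 39.8 CPM (3.56, SE 0.23), the junctional protein ESAM by 3.18, the guidance receptor ROBO4 by 1.62 and the transcription factor SOX7 by 1.56. PECAM1 rose by 0.81, KDR, the receptor VEGFR2, by 0.88, and CDH5, which encodes VE-cadherin, by 0.53. Of 20 blood endothelial genes, 10 rose and 0 fell (11 and 1 adjusted over the list alone), and of 24 pan-endothelial genes 12 rose and 1 fell (14 and 1). Camera adjusted p was 6.4e-05 and 1.6e-05, and adjusted p = 0.15 and adjusted p = 0.17 with an estimated correlation. Without siPROX1 replicate 1 the counts were 10 and 3, and 13 and 1. CDH5 missed the threshold on leaving out any library but siPROX1 replicate 3 (edgeR, Benjamini-Hochberg adjusted p from 0.0625 to 0.146). It also missed it with no low-count filter and in a fit of the siControl and siPROX1 libraries alone (edgeR, Benjamini-Hochberg adjusted p = 0.0516 and 0.109).

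Among ligands and receptors of the angiopoietin-TIE and VEGF families, the co-receptor NRP1 rose (log2 fold change 1.93, SE 0.18) and VEGFB fell (−1.19, SE 0.16). TIE1, the orphan receptor related to TIE2, had a log2 fold change of 0.43 (SE 0.16), which passed only without siPROX1 replicate 1 (0.59; edgeR, Benjamini-Hochberg adjusted p = 0.00885). ANGPT2 stood at −0.55 (SE 0.49), and at −1.64 without that library (edgeR, Benjamini-Hochberg adjusted p = 3.44e-05). Of 15 members tested, 5 rose and 2 fell (7 and 2 adjusted over the list alone), with a camera adjusted p of 0.045 and an adjusted p = 0.30 with an estimated correlation. Leaving out any 1 of the 9 libraries ended that call, with adjusted p from 0.07 (without siControl replicate 3) to 0.34 (without siPROX1 replicate 1, where 7 of 18 members tested rose and 3 fell). Dropping the low-count filter ended it as well (camera adjusted p = 0.14).

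All 26 interferon response genes rose in siPROX1, by a median of 2.30 on the log2 scale (26 adjusted over the list alone). CXCL11, a chemokine for activated T cells, rose by 4.08 (SE 0.33), IFI44L by 4.01 (SE 0.21), XAF1, an apoptosis factor, by 3.89 (SE 0.16) and IFITM1, which restricts virus entry, from 45.08 ± 14.4 to 570.9 ± 68.1 CPM (3.66, SE 0.28). Camera gave an adjusted p of 3.6e-28, and an adjusted p = 0.047 with an estimated correlation. All 26 also rose without siPROX1 replicate 1 (median 2.37). Of 21 NF-kB genes, 6 rose and 3 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.16). The chemokine CCL5 rose by 3.07, the growth factor CSF3 by 2.45, the cytokine IL6 by 2.09, at under 1 CPM in both groups, and the chemokine CX3CL1 by 1.44. CSF3 missed the threshold without siControl replicate 2 (edgeR, Benjamini-Hochberg adjusted p = 0.0584). Of 22 p53 targets, 10 rose and 0 fell (15 and 0 adjusted over the list alone), among them SPATA18 (1.76), PHLDA3 (1.75), the death receptor FAS (1.22) and the nuclease AEN (1.18). Camera adjusted p was 2e-04, and adjusted p = 0.15 with an estimated correlation. With siPROX1 replicate 1 left out, 6 NF-kB genes rose and 4 fell, and 13 p53 targets rose and 0 fell.

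In siPROX1, 8 of 23 cholesterol synthesis genes fell and the others did not pass. Log2 fold changes were −1.09 (SE 0.22) for HSD17B7, −1.05 (SE 0.26) for DHCR7, which catalyses the last step to cholesterol, −0.81 (SE 0.18) for mevalonate kinase MVK and −0.74 (SE 0.14) for lanosterol synthase LSS. The list had 0 up and 8 down (0 and 10 adjusted over the list alone), with a camera adjusted p of 1e-04 and an adjusted p = 0.37 with an estimated correlation. Leaving out siPROX1 replicate 1, 15 cholesterol genes fell, and 2 fatty acid oxidation genes rose and 6 fell. DHCR7 missed the threshold without siControl replicates 2 or 3 or siPROX1 replicate 2 (edgeR, Benjamini-Hochberg adjusted p from 0.0648 to 0.0793). Of 20 fatty acid oxidation genes, 1 rose and 5 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.20). CPT1C, a brain-type carnitine palmitoyltransferase, rose by 0.62, and HADHB, a subunit of the mitochondrial trifunctional protein, fell (−0.54).

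Contractile and matrix genes rose in part. The myosin light chain MYL9 rose from 26.89 ± 1.57 to 211.3 ± 58.7 CPM (log2 fold change 2.98, SE 0.20), the actin-binding TAGLN by 1.91 and the matricellular CTGF by 1.85. Of 21 genes of endothelial-mesenchymal transition and actin contractility, 12 rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 8e-04, and adjusted p = 0.15 with an estimated correlation). Of 30 matrix genes, 12 rose and 4 fell (13 and 6 adjusted over the list alone; camera adjusted p = 0.096), with the collagen-binding SPARC up by 1.81, the crosslinking enzyme LOXL2 by 1.61 and fibronectin, FN1, by 1.14. Markers of mural cells went both ways, with the signalling regulator RGS5 up by 3.49 to 8.365 ± 3.2 CPM and PDGFRB down (−2.53; −3.90 without siPROX1 replicate 1). Of 8 smooth muscle and pericyte markers tested, 3 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.40). With siPROX1 replicate 1 left out, counts were 11 and 4 for the transition list (camera adjusted p = 0.0022), 11 and 6 for matrix and 4 and 1 for mural genes.

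The Notch, valve, junction, shear stress, FOXO and ATF4 lists held genes moving in both directions in siPROX1, and camera called none of them (adjusted p from 0.11 to 0.85). NOTCH4, the endothelial Notch receptor, rose by 2.99 (SE 0.22), NOTCH3 by 1.97 at under 1 CPM, and the ubiquitin ligase DTX1 fell (−2.63; −3.55 without siPROX1 replicate 1). Of 20 Notch genes, 6 rose and 3 fell (6 and 3 adjusted over the list alone), and of 19 valve genes, with the TGF-beta co-receptor ENG up by 2.04, 4 rose and 5 fell (4 and 6). Of 23 junction genes 7 rose and 3 fell (8 and 5), led by the adhesion molecule JAM3 (3.42) and with the phosphatase PTPRB up by 1.17. Of 20 shear stress genes 9 rose and 4 fell (10 and 5). The quinone reductase NQO1 rose by 1.91 and ASS1, of arginine synthesis, by 2.51. CYP1B1, without a count in siControl, was at least 28.2-fold higher if each count is 1 fragment. Of 22 FOXO targets 5 rose and 2 fell (6 and 3), including the insulin receptor INSR (1.42), the transcription factor KLF2 (1.09), GADD45A (0.92) and the insulin receptor substrate IRS2 (−1.16). Of 22 unfolded protein and ATF4 genes 6 rose and 3 fell (7 and 4), including VLDLR (1.80), CHAC1 (1.39), the amino acid transporter SLC7A5 (1.11) and DDIT4, an inhibitor of mTORC1 (1.09). Median and mean differed in sign for Notch (0.08 and −0.05) and ATF4 genes (−0.11 and 0.16). Leaving out siPROX1 replicate 1 turned the balance of FOXO targets, to 6 up and 8 down (median 0.01), and turned the camera direction of the FOXO and Notch lists from higher to lower (adjusted p = 0.56 and 0.88). Without that library 7 Notch genes rose and 5 fell, with 5 and 6 for valve, 6 and 4 of 24 tested for junction, 10 and 5 for shear stress and 7 and 5 for ATF4 genes.

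Cell cycle, hypoxia and other cell type lists were not called in siPROX1 (camera adjusted p from 0.23 to 0.75). Of 30 G1/S genes 0 rose and 2 fell, and of 30 mitosis genes 1 rose and 1 fell, with the same counts adjusted over the list alone. Of 23 hypoxia and glycolysis genes 3 rose and 2 fell (4 and 2 adjusted over the list alone), with a median of −0.09, a mean of 0.02 and a camera direction of lower. Of 8 fibroblast markers 1 rose and 0 fell (2 and 0), of 5 keratinocyte markers 0 rose and 1 fell (0 and 1), with a median of −0.21 and a mean of 0.49, and of 6 leukocyte markers 1 rose and 0 fell (1 and 0). With siPROX1 replicate 1 left out, 2 mitosis genes rose and 1 fell and 3 hypoxia genes rose and 4 fell, and the other counts were as before. The abundant fibroblast gene DCN, the keratins KRT5 and KRT14 and the leukocyte genes CD3E and TYROBP, read for their level and not for a change, had no count in any of the 9 libraries. Other members of these lists were counted in every library. In CPM without TMM scaling, COL1A1 was at 6.14 to 14.1, THY1 at 3.37 to 5.81, KRT10 at 3.16 to 6.66 and LAPTM5 at 163 to 280.

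In siTIE2, CD34 rose from 24.88 ± 2.41 to 156.3 ± 5.57 CPM (log2 fold change 2.65, SE 0.12). RGCC, a cell cycle regulator, rose from 3.59 ± 0.78 to 47.37 ± 1.32 CPM (3.72, SE 0.20), the homeobox gene HLX by 3.49, SERPING1, the inhibitor of complement C1, by 3.24, IGFBP5, which binds insulin-like growth factors, by 3.11 and the netrin receptor UNC5A by 2.86. HSH2D rose by 2.80 and the interferon-induced OASL, MX2 and IFI27 by 2.66, 2.59 and 2.54. After TEK, the largest decreases reported were in SRGAP3 (to 12.5% of control), STAB2 (−2.63), CRTAC1 (−2.55), GJA4 (−2.39), the imprinted RNA H19 (−2.25) and the semaphorin receptor component PLXNA4 (−2.22), with PPFIBP2 (−2.20) and COL13A1 (−2.05) also lower. These genes had adjusted p from 9.01e-06 to 0.0206 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. UNC5A, GJA4 and COL13A1 missed the threshold on leaving out any siControl or siTIE2 library (edgeR, Benjamini-Hochberg adjusted p from 0.0507 to 0.0973).

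In siTIE2, 671 genes rose and 658 fell, 257 and 206 of them by at least 2-fold, and libraries did not overlap for 39.5% of genes, where chance gives 10%. These counts carry the wide spread of the siPROX1 libraries, since all 9 shared 1 estimate: in a fit of the siControl and siTIE2 libraries alone 1856 rose and 1768 fell. Leaving out siPROX1 replicates 1 and 3 gave 942 and 845, and 1507 and 1449. Without siControl replicates 1, 2 and 3 there were 334 and 300, 279 and 254, and 233 and 236, and without siTIE2 replicates 1, 2 and 3 there were 239 and 183, 252 and 214, and 304 and 260.

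Among lymphatic genes in siTIE2, STAB2 fell to 16.2% of control (log2 fold change −2.63, SE 0.27), and FLT4 and CCL21 fell (−0.38, SE 0.09, and −0.47, SE 0.10), while PDPN rose by 0.65 (SE 0.16). PDPN and FLT4 missed the threshold without any 1 siControl or siTIE2 library, and CCL21 without any but siTIE2 replicate 3 (edgeR, Benjamini-Hochberg adjusted p from 0.0632 to 0.132). Log2 fold changes of LYVE1 (0.43), FOXC2 (−0.76), TIE1 (−0.35), PECAM1 (0.28), CDH5 (0.18), ITGA9 (−0.11), KDR (−0.05), NR2F2 and SOX18 (both 0.00) did not pass. ANGPT2 was at 770.1 ± 4.49 CPM against 266.8 ± 15.1 CPM, a log2 fold change of 1.53 (SE 0.50; edgeR, Benjamini-Hochberg adjusted p = 0.0987). In the 6 siControl and siTIE2 libraries alone ANGPT2, LYVE1, FOXC2, TIE1 and PECAM1 passed (edgeR, Benjamini-Hochberg adjusted p from 3.67e-06 to 0.0153). ANGPT2 and LYVE1 passed without siPROX1 replicate 1, and without siPROX1 replicate 3 ANGPT2, FOXC2, TIE1 and PECAM1 (edgeR, Benjamini-Hochberg adjusted p from 9.7e-05 to 0.027). Of 22 lymphatic genes 1 rose and 3 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.97), and 5 rose and 5 fell in the siControl and siTIE2 libraries alone.

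All 26 interferon response genes rose in siTIE2 as well (26 adjusted over the list alone), by a median of 1.72, with CXCL11 up by 2.63 (SE 0.32). Camera adjusted p was 5.8e-34, and adjusted p = 0.029 with an estimated correlation. Of 22 p53 targets 5 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.0022, and adjusted p = 0.27 with an estimated correlation). PHLDA3 rose by 1.07, TP53I3 by 0.75, the ribonucleotide reductase subunit RRM2B by 0.69 and the phosphatase PPM1D by 0.67. Of 30 mitosis genes 0 rose and 2 fell (0 and 4 adjusted over the list alone), CDC20, an activator of the anaphase-promoting complex (−0.84), and the kinesin KIF23 (−0.59). That list had a median of −0.22 and a camera adjusted p of 0.013, with an adjusted p = 0.60 with an estimated correlation, and was not called without siControl replicate 3 (0.078) or siTIE2 replicate 3 (0.12). In the 6 siControl and siTIE2 libraries alone 11 p53 targets rose and 0 fell, and 1 mitosis gene rose and 6 fell. Each of the 6 genes named here from the p53 and mitosis lists missed the threshold without at least 3 of the siControl and siTIE2 libraries (edgeR, Benjamini-Hochberg adjusted p from 0.0501 to 0.158).

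Blood endothelial genes were mixed in siTIE2: CXCR4 rose by 2.23 (SE 0.13), FLT1 by 1.43 (SE 0.17) and PGF by 0.94 (SE 0.22), with 5 of 20 up and 0 down (6 and 2 adjusted over the list alone; camera adjusted p = 0.084). Of 15 angiopoietin-TIE and VEGF genes 2 rose and 3 fell (3 and 3; 0.99), the target TEK and VEGFA (−0.55) among the latter. Of 19 valve genes 3 rose and 2 fell (3 and 9; 0.22), with the connexin GJA1 up by 1.03, the guidance cue SEMA3A by 1.25 and the planar polarity cadherin CELSR1 down (−0.70). Of 20 shear stress genes 3 rose and 2 fell (3 and 3; 0.57), with caveolin CAV1 up by 0.62 and the urokinase PLAU by 1.07, and ASS1 and PTGDS down (−1.44 and −0.91). The matrix genes COL1A2 and FBLN1, which fibroblasts express strongly, rose by 1.11 to 4.979 ± 0.569 CPM and by 1.08 to 8.279 ± 1.42 CPM, as 2 of 8 fibroblast markers (2 and 0; 0.17). In the 6 siControl and siTIE2 libraries alone, higher and lower counts were 6 and 2 for blood endothelial, 3 and 4 for angiopoietin, 4 and 9 for valve, 3 and 4 of 19 for shear stress and 2 and 0 for fibroblast genes. PGF, VEGFA, SEMA3A, PLAU and PTGDS missed the threshold without any 1 siControl or siTIE2 library, PLAU and ASS1 also without siPROX1 replicate 2, ASS1 without siControl replicates 1 or 2 or siTIE2 replicates 1 or 3, CELSR1 without siTIE2 replicates 1 or 2, and CAV1 without siTIE2 replicate 1 (edgeR, Benjamini-Hochberg adjusted p from 0.0505 to 0.182).

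The remaining lists were not called in siTIE2, with counts adjusted over the list alone and the camera adjusted p in brackets. Of 24 pan-endothelial genes 0 rose and 2 fell, the target TEK among them (0 and 2; 0.99). Of 22 FOXO targets 3 rose and 1 fell (7 and 1; 0.22). Of 20 Notch genes 2 rose and 1 fell (4 and 2; 0.57), and of 23 junction genes 3 rose and 2 fell (3 and 2; 0.57). Of 30 G1/S genes 0 rose and 2 fell (0 and 2; 0.084), of 21 NF-kB genes 1 rose and 0 fell (3 and 3; 0.99), of 23 cholesterol genes 0 rose and 1 fell (0 and 1; 0.71) and of 20 fatty acid oxidation genes 0 rose and 2 fell (1 and 5; 0.084). Of 21 transition and contractility genes 3 rose and 2 fell (5 and 2; 0.22), of 30 matrix genes 4 rose and 1 fell (7 and 3; 0.46), of 23 hypoxia genes 2 rose and 2 fell (4 and 2; 0.22) and of 22 ATF4 genes 1 rose and 1 fell (2 and 1; 0.99). Among smooth muscle markers 1 of 8 rose (1 and 1; 0.64), and no keratinocyte or leukocyte marker passed (0 and 0 each; 0.88 and 0.99). In the 6 siControl and siTIE2 libraries alone, higher and lower counts were 5 and 6 for pan-endothelial, 8 and 2 for FOXO, 8 and 6 for Notch, 4 and 2 for junction, 0 and 4 for G1/S and 2 and 3 of 20 for NF-kB genes. There they were 5 and 1 for cholesterol, 2 and 6 for fatty acid oxidation, 7 and 3 for transition, 11 and 5 for matrix, 7 and 3 for hypoxia and 4 and 3 for ATF4 genes, and 1 and 1 for smooth muscle, 0 and 0 of 3 for keratinocyte and 1 and 1 for leukocyte markers. In the fit of 9, median, mean and camera direction did not share 1 sign for the lymphatic, pan-endothelial, angiopoietin, junction, NF-kB, ATF4, keratinocyte and leukocyte lists.

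**Figure D3:**
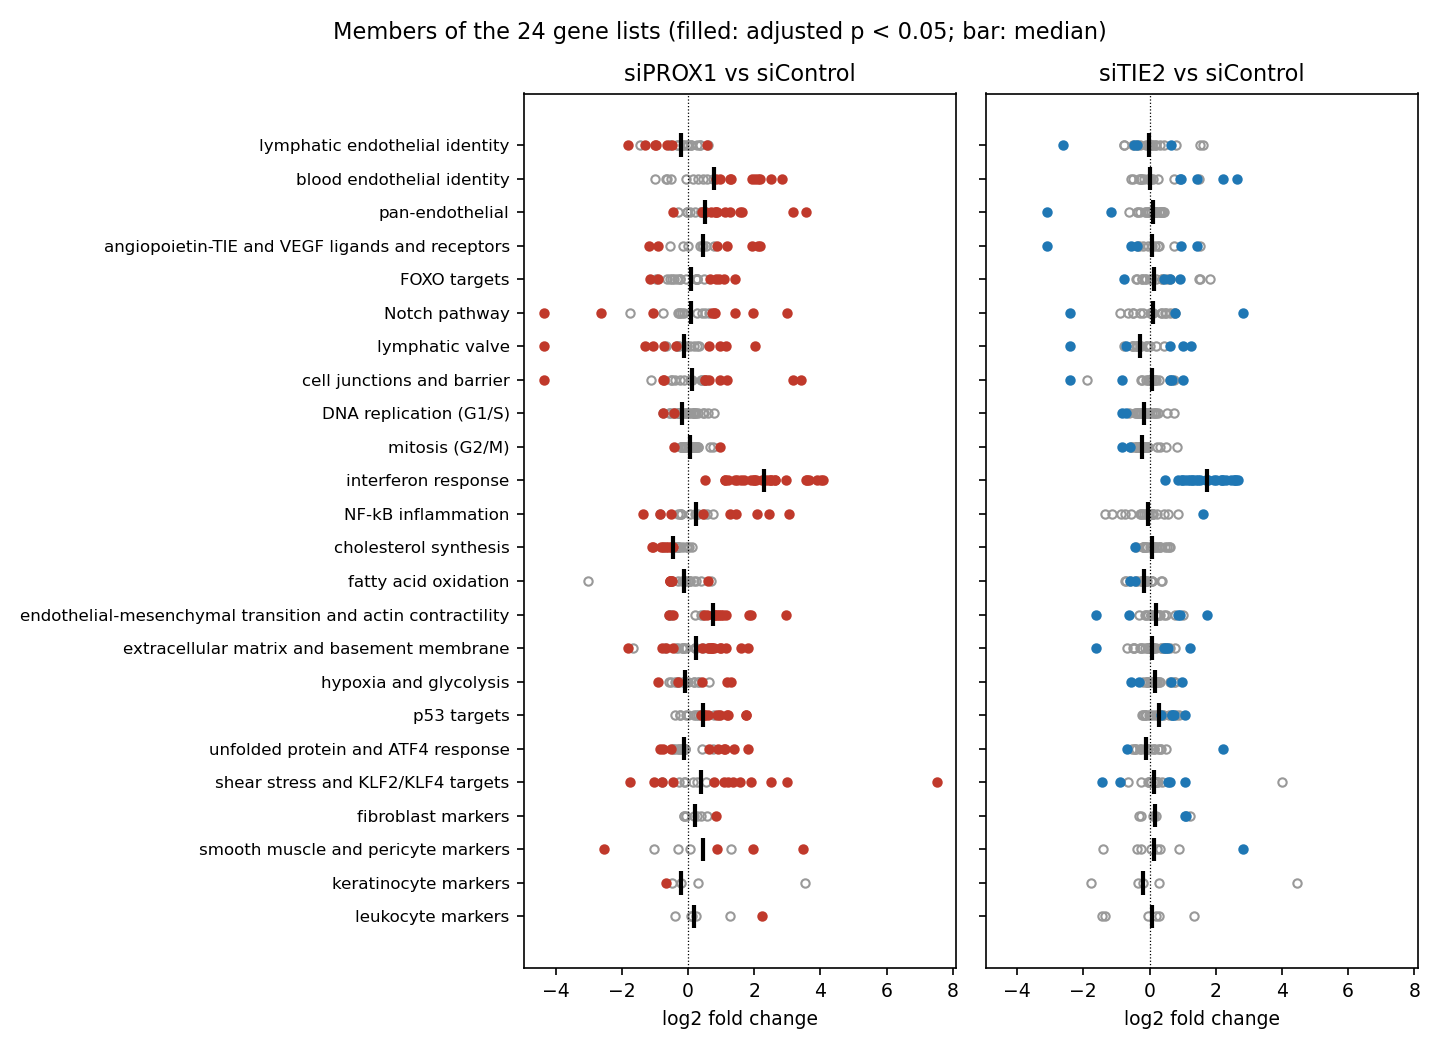
Log2 fold changes of the members of the gene lists (horizontal axis; dots, filled where the adjusted p is under 0.05; bars, list medians) in each comparison. All 26 interferon response genes are filled and above 0 in siPROX1 and in siTIE2 against siControl, with medians of 2.30 and 1.72.

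Set against each other directly, siPROX1 and siTIE2 differed in TEK (log2 fold change 3.63, SE 0.19) and, short of the threshold, in PROX1 (−1.41, SE 0.45; edgeR, Benjamini-Hochberg adjusted p = 0.0581). CLEC3B was higher in siPROX1 by 10.39, DNASE1L3 by 8.48, NOSTRIN by 6.92, CCL23 by 6.41 and FCN3 by 6.02. Their siTIE2 means were 0.0531 to 0.155 CPM, so the folds rest on few siTIE2 counts. NOSTRIN was counted in siTIE2 replicate 1 alone (5.93 without siPROX1 replicate 3) and CCL23 in siTIE2 replicate 2 alone (5.80 or 5.82 without siTIE2 replicates 1 or 3). CLEC3B was at 11.39 without siTIE2 replicate 1, DNASE1L3 at 7.87 and 10.29 without siTIE2 replicates 1 and 2, and FCN3 at 7.77 without siTIE2 replicate 2. DEPTOR, an inhibitor of mTOR, the activin antagonist FST, the retinoid transporter ABCA4, the growth factor PDGFD and PDGFRB were lower in siPROX1 (−2.59, −2.31, −2.30, −2.23 and −2.16; edgeR, Benjamini-Hochberg adjusted p from 0.0191 to 0.0429). Leaving out siPROX1 replicate 1 gave −4.61, −3.52, −3.76, −3.38 and −3.52, and PROX1 then passed at −2.06, as it did at −1.01 without siPROX1 replicate 3. All 5 missed the threshold in a fit of the siPROX1 and siTIE2 libraries alone and without any 1 siTIE2 library, all but FST without siPROX1 replicate 2, DEPTOR and ABCA4 without any siControl library, and PDGFRB without siControl replicates 2 or 3 (edgeR, Benjamini-Hochberg adjusted p from 0.0523 to 0.117).

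In this comparison 1690 genes were higher in siPROX1 and 1147 lower, 804 and 308 of them by at least 2-fold, and libraries did not overlap for 39.3% of genes, where chance gives 10%. The counts were 2306 and 2022 without siPROX1 replicate 1 and 966 and 290 without siPROX1 replicate 2. In a fit of the siPROX1 and siTIE2 libraries alone they were 1042 and 314. They were 884 and 327, 841 and 242, and 866 and 275 without siTIE2 replicates 1, 2 and 3, and 1292 and 666 without siControl replicate 3.

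Interferon response genes were higher in siPROX1 than in siTIE2 for 14 of 26 members, with 0 lower and a median of 0.60 (16 and 1 adjusted over the list alone; camera adjusted p = 2.4e-06, and adjusted p = 0.30 with an estimated correlation). Of 23 cholesterol synthesis genes 0 were higher and 10 lower (0 and 17; 4.1e-06, and adjusted p = 0.39 with an estimated correlation). Of 24 pan-endothelial genes, the siTIE2 target TEK included, 13 were higher and 2 lower (14 and 2; 2.4e-06, and adjusted p = 0.30 with an estimated correlation). Of 20 blood endothelial genes 9 were higher and 1 lower (9 and 3; 0.012, and adjusted p = 0.32 with an estimated correlation). Of 15 angiopoietin-TIE and VEGF genes, TEK included, 7 were higher and 2 lower (8 and 3; 0.014, and adjusted p = 0.30 with an estimated correlation). Of 21 transition and contractility genes 9 were higher and 3 lower (9 and 5; 0.029, and adjusted p = 0.30 with an estimated correlation), and of 30 mitosis genes 3 and 0 (1 and 0; 0.0066, and adjusted p = 0.49 with an estimated correlation). Without siPROX1 replicate 1 the blood endothelial, angiopoietin and transition lists were no longer called (adjusted p = 0.051, 0.20 and 0.067), and the angiopoietin list was lost also without siControl replicate 2 (0.05), siPROX1 replicate 2 (0.051) or siTIE2 replicate 2 (0.15).

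No other list was called between siPROX1 and siTIE2. Of 22 lymphatic genes 3 were higher and 7 lower (5 and 9 adjusted over the list alone; camera adjusted p = 0.11), and of 21 NF-kB genes 7 and 3 (8 and 4; 0.059), called without siPROX1 replicate 3 (0.04) or siTIE2 replicates 1 (0.047) or 3 (0.044). Higher and lower counts were 4 and 6 of 22 FOXO targets (5 and 6), 5 and 4 of 20 Notch genes (5 and 8), 5 and 4 of 19 valve genes (5 and 5) and 3 and 2 of 23 junction genes (4 and 2). They were 1 and 1 of 30 G1/S genes (1 and 1), 2 and 1 of 20 fatty acid oxidation genes (2 and 1), 7 and 5 of 30 matrix genes (8 and 8), 1 and 4 of 23 hypoxia genes (1 and 4) and 5 and 1 of 22 p53 targets (7 and 2). They were 5 and 4 of 22 ATF4 genes (5 and 5), 8 and 3 of 20 shear stress genes (8 and 6), 2 and 1 of 8 smooth muscle markers (2 and 1) and 1 and 0 of 6 leukocyte markers (1 and 0). No fibroblast or keratinocyte marker passed (0 and 0 each), and camera adjusted p for these lists ran from 0.19 to 0.88. Without siPROX1 replicate 1 the balance turned for Notch (5 and 7) and junction genes (3 and 4 of 24 tested), and the camera direction of the junction list turned to lower (adjusted p = 0.85). Median and mean differed in sign for fatty acid oxidation (0.02 and −0.02) and smooth muscle markers (−0.11 and 0.20).

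In both knockdowns CD34, CXCR4, FLT1, PGF and CXCL11 rose and GJA4, SRGAP3, STAB2 and CCL21 fell. Among 16815 genes, 424 rose in both and 335 fell in both, where independent lists would share 75.4 and 51.4. Simulated unchanged groups against shared simulated controls had a mean of 0.01 each. With no gene changed, almost none could be called there. That mean therefore does not measure how far shared controls raise the overlap of called genes. By contrast 36 rose in siPROX1 and fell in siTIE2, against 74 for independent lists, and 0 fell in siPROX1 and rose in siTIE2, against 52.4. Without siPROX1 replicate 1 these 4 counts became 451, 350, 101 and 96, against 118, 91, 105 and 101. Without siPROX1 replicate 3, 806 rose in both, 640 fell in both and 64 and 4 went opposite ways. On leaving out any 1 siControl or siTIE2 library, 187 to 262 rose in both, 112 to 163 fell in both and 10 to 15 rose in siPROX1 and fell in siTIE2.

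Across genes, the log2 fold changes of both knockdowns correlated at r = 0.506 and rho = 0.38. Simulated unchanged groups with shared simulated controls gave a mean r of 0.487 and rho of 0.45. Those simulated controls carried the spread of the joint fit, wide siPROX1 spread included, and not that of siControl alone. The covariance was 0.325 against 0.0869 in the simulation, a difference of 0.238, and 0.317 without siPROX1 replicate 1 (r = 0.36). With 3 control libraries no split left at least 2 in each part, so part of the excess of shared calls over independent lists may come from the shared controls. Mixed reads in siPROX1 replicate 1, a candidate given below, may add to the agreement too. Without that library 451 and 350 genes were shared, against 118 and 91 for independent lists. Opposite calls were then 101 and 96, against 105 and 101, so their lack was gone.

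**Figure D4:**
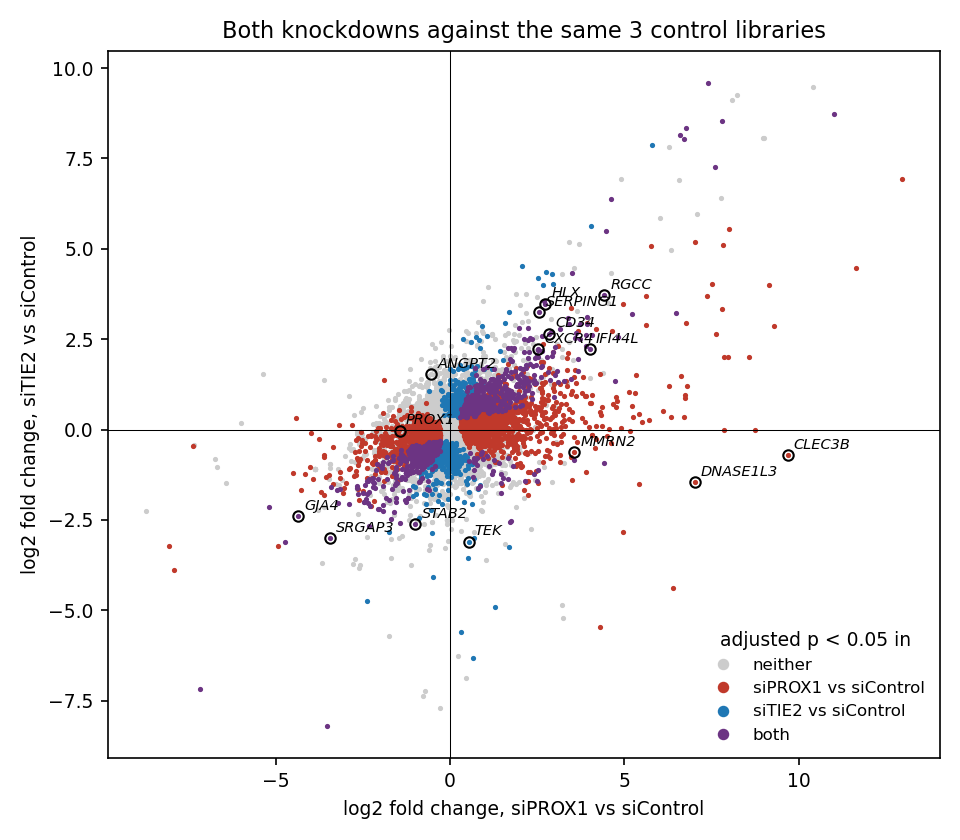
Log2 fold change against siControl in siPROX1 (horizontal axis) and siTIE2 (vertical axis) for the genes tested, 1 point per gene, coloured by the comparisons in which they were called. Of the called genes, 424 lie above 0 in both, 335 below 0 in both, 36 above 0 in siPROX1 and below 0 in siTIE2, and 0 the other way.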

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

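No alternative was chosen after the results were seen. No result past its threshold changed direction. Short of it, values near 0 changed sign on leaving out 1 library, among them PDPN and ITGA9 in siPROX1 and PROX1 (0.15 and 0.03), KDR, NR2F2 and SOX18 in siTIE2, each against siControl. Without siPROX1 replicate 1 so did the camera direction of the FOXO and Notch lists in siPROX1, of the lymphatic, NF-kB and ATF4 lists in siTIE2 and of the junction list between them. Of named genes' values, 2420 kept their side of the threshold, 186 lost it and 21 gained it. Of gene list results, counted for lists that camera called or with at least 25% of members past the threshold, 543 kept it, 43 lost it and 16 gained it. Of these, 16 were lost with an estimated correlation, and 12 were gained and 1 lost with fry, which tests whether a list's genes move on balance and not whether they differ from other genes. Among the lists not counted, fry gave adjusted p under 0.05 for G1/S in siPROX1 (0.021), for Notch (0.022), G1/S (0.015), fatty acid oxidation (0.012), hypoxia (0.025) and smooth muscle genes (0.033) in siTIE2, and for hypoxia between siPROX1 and siTIE2 (0.014).

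PROX1 in siPROX1 against siControl stayed at −1.44 but missed the threshold with robust dispersion (edgeR, Benjamini-Hochberg adjusted p = 0.0521) and with only the 6 libraries compared (−1.44; edgeR, Benjamini-Hochberg adjusted p = 0.113). Leaving out 1 library gave −2.09 to −1.04. TEK in siPROX1 passed with the stricter filter (0.53; edgeR, Benjamini-Hochberg adjusted p = 0.0461), with the replicate block (0.50; 0.0481) and with DESeq2 (0.52; 0.0233), and ranged from 0.33 to 0.71 on leaving out 1 library. The cause was not tested.

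At an adjusted p under 0.01, counts of higher and lower genes were 1106 and 567 for siPROX1 and 230 and 194 for siTIE2 against siControl. With only the 6 libraries compared, 1327 were higher and 705 lower in siPROX1, and 1856 and 1768 in siTIE2, each against siControl. Between siPROX1 and siTIE2 the counts were 1042 and 314, with 76.8% higher against 59.6% in the fit of 9. DESeq2 gave 1222 and 1163 for siTIE2 and 1770 lower in siPROX1 than in siTIE2. A fit of the siControl and siPROX1 libraries alone ended the calls of RELN and DHCR7 (edgeR, Benjamini-Hochberg adjusted p = 0.0542 and 0.0534). For PLAU and PTGDS in siTIE2, no low-count filter and robust dispersion each ended the call (edgeR, Benjamini-Hochberg adjusted p from 0.0503 to 0.059). Leaving out 1 library gave 1203 to 2304 higher and 716 to 1853 lower for siPROX1, 233 to 1507 and 183 to 1449 for siTIE2, and 841 to 2306 and 242 to 2022 between them. It gave 187 to 806 genes higher in both, 112 to 640 lower in both, 10 to 101 higher in siPROX1 and lower in siTIE2, and 0 to 96 the other way. Fewer libraries lower the power, and dropping the widely spread siPROX1 libraries narrows the shared spread; other causes were not tested.

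The replicate block gave 1715 and 1227, 540 and 537, and 1448 and 1036 genes, and ended the camera call of the lymphatic list in siPROX1 against siControl (adjusted p = 0.055). It also ended the calls of PDPN, FLT4, PGF, PHLDA3, ASS1 and PTGDS in siTIE2 against siControl (edgeR, Benjamini-Hochberg adjusted p from 0.0504 to 0.0892), and no call of a named gene, or of a list that camera had called, between siPROX1 and siTIE2. The replicate numbers do not pair siControl with either knockdown: deviations of same-numbered libraries correlated at −0.166 to 0.164 between siControl and siPROX1 and at −0.074 to −0.025 between siControl and siTIE2, and siControl replicate 1 correlated best with siPROX1 replicate 3 (0.27).

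Depth was 87030670 to 156382832 counts, which leaves genes with few counts in a group, such as CHN2 in siControl or NOSTRIN in siTIE2, with folds that rest on 1 library. Lower depths were not tested.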

Other observations

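The tests of mixed reads, incomplete knockdown, a TIE2-loss-like response, the interferon pattern and other splits were chosen after the results were seen; those of GC content and transcript length were fixed before their result was seen.

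CD14, the co-receptor for lipopolysaccharide, rose in siPROX1 as the 1 called gene of the leukocyte list, from 0.769 CPM in siControl to 3.54 CPM (log2 fold change 2.23, SE 0.49; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0109), and was at 0.291 CPM in siTIE2. It was named after its values were seen. CD68 stood at 85.1, 91.8 and 106 CPM and LAPTM5 at 199, 230 and 198 CPM in siControl, siPROX1 and siTIE2, while PTPRC stayed at or below 0.0187 CPM in every library. Of the interferon genes themselves, IFNB1, IFNA1, IFNL1, IFNL2 and IFNL3 had no count in any of the 9 libraries, IFNE had 0 to 2 counts per library, and IFNK had 10, 29 and 43 counts in siControl, 8, 6 and 2 in siPROX1 and 12, 20 and 8 in siTIE2.

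The first pattern is that siPROX1 replicate 1 lies between the other siPROX1 libraries and siTIE2. Of 53 genes counted in siTIE2 replicate 1 and absent from the other siTIE2 libraries, 84.9% had a count in siPROX1 replicate 1, against at most 34% in any other library. A non-negative fit by the other 8 libraries gave it a summed siTIE2 weight of 0.5, which argues against incomplete PROX1 knockdown alone. In genes of at least 20 CPM, siTIE2 replicates 2 and 3 together took 0.02 (0 to 0.06 over 200 draws) and siTIE2 replicate 1 took 0.46. These weights cannot decide on a TIE2-loss-like response of that culture, because they can fall on 1 of several like libraries. In the fit by the other 8 libraries, siControl replicate 1 took 0.8 of siControl replicate 3 and 0.01 of siControl replicate 2. A culture paired with siTIE2 replicate 1 could also load on that library. From the shared genes above, a candidate explanation is mixing of RNA, library or reads of siTIE2 replicate 1 into siPROX1 replicate 1. The weights would put it at close to equal parts, and at which step it may have happened was not tested.

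The second pattern is that all 26 interferon response genes rose with both siRNAs. Mixed reads cannot be the whole cause in siPROX1, since 26 members were higher without siPROX1 replicate 1. Leukocyte RNA is argued against by the summed level of PTPRC, TYROBP, CD52 and LYZ, at most 0.421 CPM in the knockdown libraries. Innate sensing of the targeting siRNAs beyond that of the control siRNA cannot be told apart from an effect of losing each target, because 0 of the libraries analysed had no siRNA or a further siRNA against the same target. A response to the loss of PROX1 or TIE2 stays open as well.

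The third pattern is the gap between siPROX1 replicates 2 and 3, whose log2 ratio across genes had an SD of 0.558, against 0.163 to 0.317 for pairs within the other groups. Removing the trend with GC content lowered that SD by 4.71%, and with transcript length by 2.52%, so neither is the whole cause. PROX1 itself differed, at 175 and 67.2 CPM, and a stronger knockdown in replicate 3 was not tested. In the non-negative fit by the other 8 libraries, siPROX1 replicate 3 took 0.32 of siControl replicate 1. Deviations of that pair from their group means correlated at 0.27. Genes counted in siControl replicate 1 alone of its group had a count in 32% of cases in siPROX1 replicate 3, against 44% in siPROX1 replicates 1 and 2. A shift shared with siControl replicate 1 was not tested further.

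With 6 libraries in 10 splits of 3 and 3, no share under 0.05 can be reached. The real split called 3203, 1329 and 2837 genes for siPROX1 against siControl, siTIE2 against siControl and siPROX1 against siTIE2, 1 of 10 splits each. The highest of the other splits called 0. Every other split put libraries of both conditions into each group, so differences between the conditions widened the spread and few calls could arise. The 0 is therefore no measure of chance.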
